A study of Rattus norvegicus with 8 samples.

How the data were processed

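Total RNA from rat alveolar type II (ATII) cells was measured on 8 Affymetrix arrays, 4 of cells given an adenovirus carrying green fluorescent protein (AdGFP) and 4 of cells given an adenovirus carrying a constitutively active mutant of HIF1a (AdHIF1a). The cells came from 4 male Sprague Dawley rats, and each rat gave 1 well of each virus on its own extraction day, per the series' design. The 4 values of a group are therefore separate animals. Rat and extraction day coincide and cannot be separated, and a difference within a rat is free of both. Per the labels' protocols, freshly isolated cells were incubated with virus at a multiplicity of infection of 20 for 3 h in medium with 2% fetal bovine serum. They were then plated on a mixture of 80% rat tail collagen and 20% Matrigel in medium with 5% rat serum, and RNA was taken 24 h later with a column kit and labelled with biotin.

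The deposited values are log2 signals per probe set, given to 2 decimals for 36685 probe sets on each array. Per the submitters' processing notes they were made with Affymetrix Expression Console. The summarization and normalization algorithm, the software version and the genome build are not given in the sources used here. The log2 scale was read from the values, which run from 1.42 to 13.57. The values are not centred per gene. The array medians were 5.13, 5.00, 5.07 and 5.04 for the AdGFP wells of rats 1 to 4, and 5.02, 5.19, 5.16 and 5.20 for their AdHIF1a wells. The upper quartiles lay between 7.62 and 7.68, so the arrays had been brought to a common scale before deposit. No further scaling was applied in the main test. A common scale fixes the bulk of the signal, so a general rise or fall of all transcripts in 1 group would not be seen, and low signals lie close to the floor of the array, where folds are compressed. The files hold no detection calls. The number of arrays limits the precision.

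Probe sets were named from the platform annotation. Of the probe sets, 18511 carried 1 gene symbol, 575 carried several and 17599 carried none. Probe sets with several symbols or none entered no gene count. The gene identifiers of 18394 of the singly named probe sets matched the rat reference annotation (GRCr8), which changed 0 symbols. Where a gene had several probe sets, the one with the highest mean over the 8 arrays stood for it, which left 18166 genes. The array's genome build is not given in the sources used here, so no coordinates are reported.

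The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the rat as a fixed block and no filter on dim probe sets. The difference is AdHIF1a minus AdGFP in log2 units, its standard error (SE) is the moderated one, intervals are 95% confidence intervals, and p-values are two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 18166 genes. The pairing comes from the series' design, which gives 1 well of each virus per rat. The deviations of the 2 wells of a rat from their group means correlated across genes at 0.18 to 0.26, against -0.22 to 0.08 for wells of different rats; genes are not independent replicates. No arrays held the same values, and at most 1.95% of the values of any pair of arrays were equal to 2 decimals.

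Before the data were examined, 22 gene lists with 513 entries were written down, for HIF pathway components, HIF targets, lung epithelial states, processes in the cells and markers of other cell types. Of the entries, 462 matched a measured gene and the others were not analysed here. Each list was tested with limma's camera (preset correlation between genes of 0.01, two-sided, adjusted over the 22 lists), which compares its genes with all other genes. Members past the threshold were counted with p adjusted over all genes and with p adjusted over the list alone. Camera with a correlation estimated for each list, and fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were alternatives.

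The genes to be named were fixed by a rule. These were Hif1a, then the 12 genes with the largest increase and the 12 with the largest decrease among those called and moving the same way in all 4 rats. In each list the 4 called members with the smallest adjusted p and the member with the largest difference were named, and in a list with no call the 2 members with the smallest p. A further 9 genes were named whatever their result (Cxcr4, Cxcl12, Vegfa, Slc2a1, Pdk1, Sftpc, Sftpb, Ager and Mki67). Where 5 or fewer members of a list were called in a direction, those outside the rule were also named, after their values were seen.

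The alternatives were no block, the rat as a random block, quantile normalization, centring of each array on its median, filters on dim probe sets at the median and at the lower quartile of the probe sets, array weights, a trended and robust variance prior, the mean of all probe sets of a gene, an adjusted p under 0.01, a minimum of 1.5-fold, and the omission of each rat in turn. The comparison was repeated for all 35 splits of the 8 arrays into 4 and 4, of which 3 part no rat's wells and give no contrast within rats.

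The test was tried on simulated data. In 5 runs with 200 changed genes each among 18166, normal noise was drawn with the moderated spread of each gene from the limma fit. Of the genes changed by 0.5 log2 units 8.66% were called, 89.6% of those changed by 1 and 99.1% of those changed by 2, and 0.756% of all calls were false. The moderated spread is drawn towards a common value, so the simulated genes were more alike in spread than the measured ones and these shares may not carry over. Of 250 simulated lists with no shift, 4 had a camera p under 0.05, and 5 of 5 lists shifted by 0.5 were found. With an estimated correlation these counts were 0 of 250 and 5 of 5. These shares hold for that number of changed genes, since more calls loosen the adjusted threshold. The simulated noise was independent between genes, whereas the correlation estimated from the data reached 0.69 for the cell cycle list. The simulated lists therefore do not show how often camera errs in lists whose genes are so correlated.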

Results

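Gene expression was measured in freshly isolated rat alveolar type II (ATII) cells, the surfactant-secreting epithelial cells of the lung, after transduction with AdHIF1a or with the control virus AdGFP. HIF1a is the oxygen-regulated subunit of hypoxia-inducible factor 1, which is normally degraded when oxygen is present, and the virus carried a mutant that is constitutively active. Each of 4 rats gave 1 well of each virus, so that 8 arrays formed 4 pairs, and all differences below are AdHIF1a minus AdGFP within rats, in log2 units ± SE from the paired limma fit (4 rats). Arrays of the same virus correlated at 0.991 to 0.996 across the 18166 genes and arrays of different viruses at 0.977 to 0.986. Of the variance over genes, 57.5% lay between the viruses, 26.1% between the rats and 16.4% was left over.

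The comparison asked which genes change in ATII cells when constitutively active HIF1a is expressed. Most genes of glycolysis and glucose uptake and most other known targets of HIF rose in the wells labelled AdHIF1a, with 16 of 18 and 29 of 35 measured members higher and 0 lower, and median differences of 1.61 and 1.31. The vascular signals Adm, Apln, Pgf and Vegfa also rose, as did the chemokine receptor gene Cxcr4 (5.56-fold). Most measured markers of alveolar type I cells, the flat gas-exchange cells that ATII cells can turn into, were lower (14 of 23, Ager by 2.11-fold and Aqp5 by 5.63-fold), and the mitotic kinase gene Cdk1 and the proliferation marker Mki67 fell 2.43-fold and 2.92-fold. The calls of Cdk1 and Mki67 were each lost without rat 2, 3 or 4, and Mki67 differed by only -0.28 in rat 1. Cdk1 ended near the floor (4.72), so its fold is not an exact size. Markers of ATII cells went both ways, with the surfactant protein genes Sftpa1 and Sftpb higher and Napsa, Muc1 and the transcription factor Foxa2 lower.

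Of 18166 genes tested, 1032 were higher and 1411 lower in the wells labelled AdHIF1a, or 13.4% of all genes. Each of the 2443 genes moved in the same direction in 4 of 4 rats. With 4 pairs a call at this threshold requires that, so it is no separate evidence of agreement between rats. At least 2-fold differences were seen for 304 of the higher and 315 of the lower genes, and at least 4-fold differences for 72 and 25. The median difference over all genes was -0.005. The number of calls depended on the rats included, with 775 higher and 1231 lower without rat 1, 315 and 246 without rat 2, 517 and 601 without rat 3, and 327 and 304 without rat 4, so that the excess of lower calls turned without rat 2 or rat 4. Median centring gave 635 higher and 1324 lower genes, and in these fits no shared call changed sign.

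The 12 largest increases were led by Car12, a membrane-bound carbonic anhydrase, which went from a log2 signal of 4.73 ± 0.06 to 10.68 ± 0.11 (SD, 4 rats), a 61.5-fold difference (95% interval 52.6 to 72.0, adjusted p = 5.2e-05, probe set 17845415). Stc1, which encodes the secreted glycoprotein stanniocalcin, rose 44.4-fold (36.1 to 54.6, adjusted p = 0.000149, probe set 17699814). The transmembrane protein genes Tmem255b and Tmem45a rose 38.2-fold and 33.8-fold, and Ascl2, a basic helix-loop-helix transcription factor, rose 27.4-fold. Crct1, a gene of the epidermal differentiation complex, rose 26.0-fold. Duox2, an oxidase that makes hydrogen peroxide, rose 18.3-fold, and Ciart, a repressor of the circadian clock, rose 18.1-fold. Adm, the gene of the vasodilator peptide adrenomedullin, rose 17.0-fold (11.6 to 25), and Cntfr, the receptor subunit for ciliary neurotrophic factor, rose 16.9-fold. Foxred2, a flavoprotein of the endoplasmic reticulum, rose 14-fold, and Eno2, the neuronal form of the glycolytic enzyme enolase, rose 13.5-fold (9.64 to 18.8). Adjusted p in limma was at most 0.00132 for these 12 genes. The AdGFP signals of Car12, Tmem45a (4.79), Ascl2 (4.79) and Ciart (4.76) lay below the medians of all arrays, near the floor and without detection calls, so the folds and ranks of these genes are not exact sizes.

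The 12 largest decreases were smaller. Sult1a1, a sulfotransferase of phenolic compounds, was 9.66-fold lower (95% interval 4.55 to 20.5, limma adjusted p = 0.0105, probe set 17637216), and Slco2a1, the prostaglandin transporter, was 7.77-fold lower (5.40 to 11.2, adjusted p = 0.00248, probe set 17847021). Sgcd, which encodes delta-sarcoglycan, Akap5, an anchoring protein for protein kinase A, and Aqp5, the water channel of type I cells, were 5.90-, 5.81- and 5.63-fold lower. The serine protease gene Prss22 was 5.47-fold lower, Gpr158, a gene of the G protein-coupled receptor superfamily, 5.36-fold, and the receptor tyrosine kinase-like gene Ror1 5.25-fold. Tagln, an actin-binding protein abundant in smooth muscle, was 5.11-fold lower and Nrep 4.91-fold. Scn3b, a sodium channel subunit, was 4.79-fold lower and Sparc, a matricellular protein, 4.52-fold. The signal of Scn3b ended near the floor in the AdHIF1a wells (4.78), so its fold is not an exact size. The call of Sult1a1 was lost without rat 2 (adjusted p = 0.0603), and so was that of Aqp5 (adjusted p = 0.0607).

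**Figure D1:**
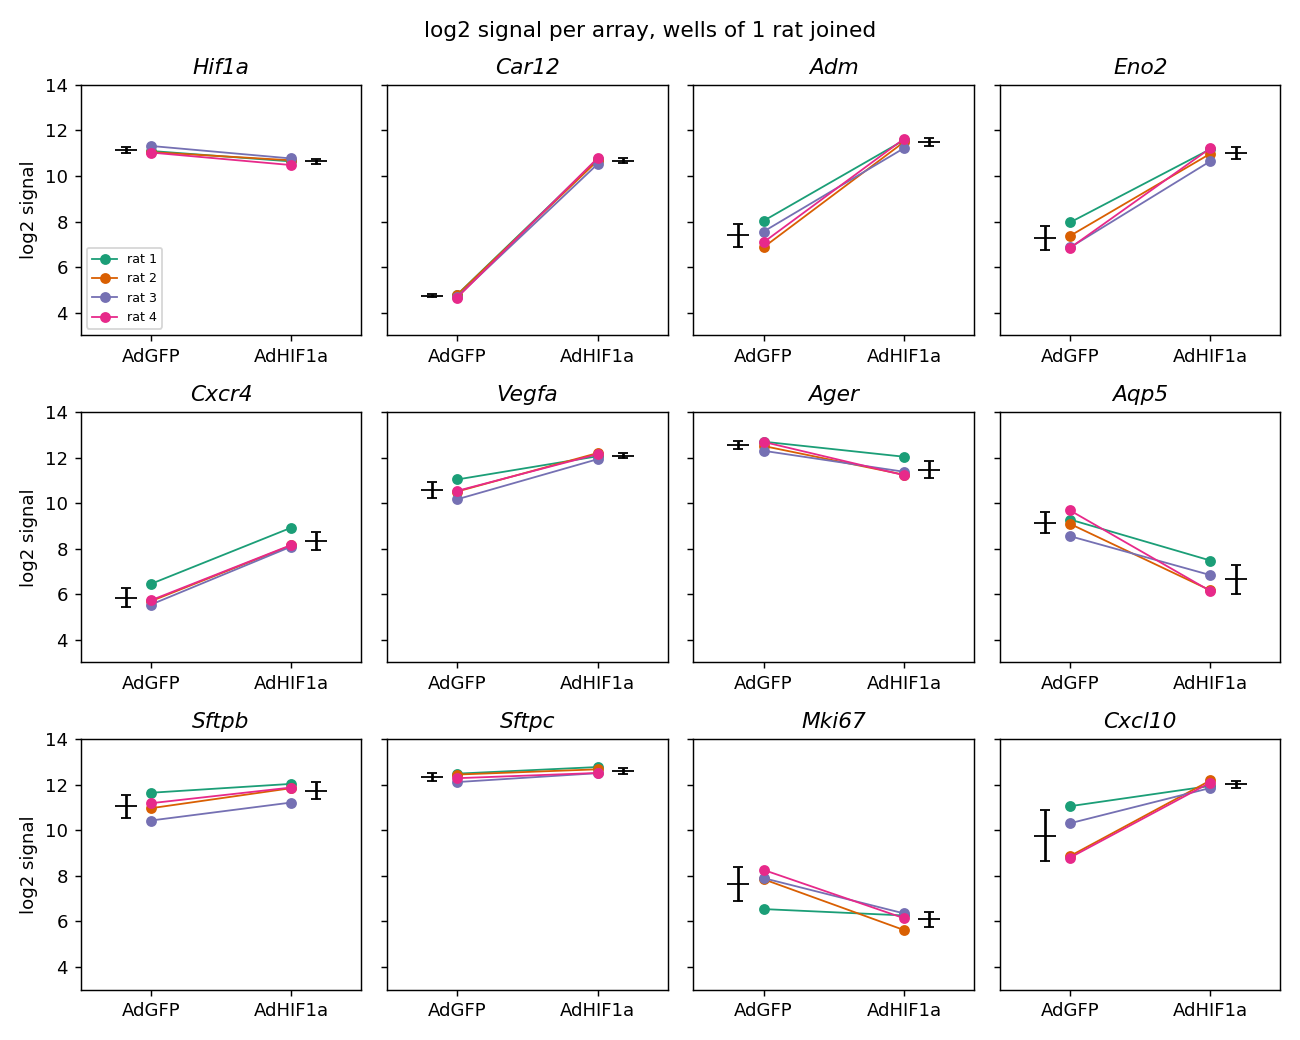
Log2 signal (vertical axis) of 12 genes in the AdGFP and AdHIF1a wells, with a line joining the 2 wells of each of 4 rats; black bars give the mean ± SD of a group. Car12, Adm, Eno2, Cxcr4 and Vegfa were higher and Aqp5 and Ager lower in the AdHIF1a well of all 4 rats, while Mki67 fell by 0.28 in rat 1 and by 2.23 in rat 2.

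Hif1a itself gave a lower signal in the wells labelled AdHIF1a on its rat probe set (17816622). The mean went from 11.12 ± 0.13 to 10.64 ± 0.12 (SD), a difference of -0.48 ± 0.08, or 1.39-fold (95% interval 1.21 to 1.61, adjusted p = 0.0217), and was negative in 4 of 4 rats. Neither the species of the transgene nor the probe sequences are given in the sources used here, so this probe set does not check the labels of the wells. The call of Hif1a was lost without rat 2 (-0.52, adjusted p = 0.0875), rat 3 (-0.46, 0.0869) or rat 4 (-0.46, 0.113).

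Among 12 measured HIF pathway components, 5 were higher, 2 lower and 5 not past the threshold, and adjusted over the list alone 6 were higher and 2 lower. Egln3 and Egln1, prolyl hydroxylases that mark HIF for degradation, rose by 2.12 ± 0.17 and 1.89 ± 0.09. The transcriptional co-regulator Cited2 rose by 1.33 ± 0.14 and the inhibitory HIF subunit gene Hif3a by 1.22 ± 0.13. Vhl, the ubiquitin ligase component that recognises hydroxylated HIF, rose by 0.56 ± 0.13 (adjusted p = 0.0418), and Arnt2, a partner subunit, fell by 0.54 ± 0.09 (adjusted p = 0.0190); both lay outside the naming rule. The list as a whole was not called (median 0.17, camera adjusted p = 0.125), except after median centring (0.0105) or with fry (0.00205).

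Of 18 measured genes of glycolysis and glucose uptake, 16 were higher and 0 lower, and 17 were higher adjusted over the list alone. The glucose transporter gene Slc2a1 rose by 1.19 ± 0.09 from an already high level of 11.63 ± 0.14 (SD), or 2.29-fold. Hk2, which phosphorylates glucose, rose by 1.90 ± 0.09, Pfkp, a subunit of phosphofructokinase, by 2.11 ± 0.10, and Pgm1, which links glycogen to glycolysis, by 1.69 ± 0.08. Pdk1, a kinase that shuts off pyruvate dehydrogenase, rose by 1.98 ± 0.09, or 3.94-fold. Median differences of the list were 1.35, 1.64, 1.71 and 1.61 in rats 1 to 4. The list was called by camera (median 1.61, adjusted p = 3.12e-18), and this call was lost with a correlation estimated from the data (adjusted p = 0.0777 with an estimated correlation).

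The other canonical HIF targets showed 29 of 35 measured members higher and 0 lower, and 30 higher adjusted over the list alone. Besides Car12, the named members were Stc2, a second stanniocalcin gene (3.42 ± 0.15), the collagen cross-linking enzyme Loxl2 (2.72 ± 0.11) and the mitochondrial protein gene Fam162a (2.19 ± 0.10), each with a limma adjusted p of at most 0.000882. The median difference of the list was 1.31, and 1.32, 1.28, 1.05 and 1.49 in rats 1 to 4. This list was called with the preset correlation (camera adjusted p = 2.62e-26) and with an estimated one (adjusted p = 0.0397). Of the 7 lists called by camera with the preset correlation, it was the only one called with an estimated correlation. The correlation estimated for this list was 0.0125, near the preset 0.01, and the adjusted p still rose this far. With so few arrays the estimated form may have less power, so a call lost under it does not show that a list is unchanged. In the simulations, however, it found 5 of 5 shifted lists. The estimated correlations were 0.55 for type I markers, 0.69 for the cell cycle, 0.42 for mitochondrial and 0.61 for interferon genes. The preset 0.01 assumes far less correlation than these lists showed, so their calls with it are not secure. Of the 32 splits of the arrays that give a contrast within rats, 10 called at least 7 lists with the preset correlation, the true grouping included, as did 4 of the 8 that part the wells of all 4 rats. Other splits can keep part of the virus difference, so these counts do not measure chance alone. Among the 8, however, the splits that exchange labels within 2 of the 4 rats cancel its average, and they called 2, 8 and 4 lists.

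Angiogenic and chemotactic signals went both ways, with 6 of 22 measured members higher and 2 lower (9 and 4 adjusted over the list alone). Apln, a peptide ligand that acts on endothelial cells, rose by 3.63 ± 0.12 and Pgf, placental growth factor, by 3.18 ± 0.20 from a low signal of 4.71 ± 0.29 (SD). Vegfa, the main endothelial growth factor, rose by 1.52 ± 0.15, or 2.87-fold, from a level of 10.56 ± 0.36 (SD). Cxcr4, the receptor of the chemokine Cxcl12, rose by 2.48 ± 0.08, or 5.56-fold (adjusted p = 0.000308). Cxcl12 itself rose by 1.23 ± 0.24 from a low signal of 4.41 ± 0.20 (SD), and its call was lost without rat 2 (adjusted p = 0.0928) or rat 4 (adjusted p = 0.120). The 2 lower genes, outside the naming rule, were Nrp1, a co-receptor of vascular growth factors (-0.87 ± 0.13), and the growth factor gene Pdgfa (-0.53 ± 0.08). The list was not called (median 0.05, mean 0.68, camera adjusted p = 0.0609), but passed without the rat as a block (0.0476), after median centring (0.00277), with the filter at the lower quartile (0.0441), with fry (0.00159) and without rat 2 (0.0431) or rat 4 (0.0257).

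Markers of ATII cells were split, with 2 of 21 higher, 8 lower and 11 not past the threshold, or 4 higher and 13 lower adjusted over the list alone. The surfactant protein gene Sftpa1 rose by 0.89 ± 0.10. Sftpb rose by 0.69 ± 0.11 from 11.06 ± 0.51 (SD), with adjusted p = 0.0168 in the paired fit and 0.128 without the rat as a block, 0.0968 with a random block and 0.0736 to 0.0895 without rat 2, 3 or 4. Sftpc differed by 0.29 ± 0.08 (adjusted p = 0.0840), and passed the threshold with the filter at the median (0.0382) and with the trended prior (0.00849). The aspartic protease gene Napsa, which acts in surfactant protein processing, fell by 1.52 ± 0.18, the membrane mucin gene Muc1 by 1.31 ± 0.11 and Foxa2 by 0.72 ± 0.10. Napsa was not called without rat 2 (adjusted p = 0.0509), nor Foxa2 without rat 2 (0.0670) or rat 4 (0.0636). The list median was -0.44 (camera adjusted p = 0.0544), and the list passed without the rat as a block (0.0351), with a random block (0.0368), after median centring (0.0432), with the trended prior (0.0438), with fry (0.0432) and without rat 2, 3 or 4 (0.0431, 0.0247 and 0.0379).

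Markers of alveolar type I cells were lower for 14 of 23 measured genes and higher for 3, and adjusted over the list alone 19 were lower and 3 higher. Ager, the receptor for advanced glycation end products and an abundant type I marker, fell by 1.08 ± 0.15 from 12.55 ± 0.19 (SD). Aqp5 and Akap5 were given above, the LIM domain gene Lmo7 fell by 1.09 ± 0.09 and Timp3, an inhibitor of metalloproteinases, by 0.98 ± 0.12. The 3 higher genes were Igfbp2 (2.03 ± 0.25), Vegfa and Cav2 (0.94 ± 0.14), of which Igfbp2 and Cav2 were outside the naming rule. Medians of the list were -0.57, -1.11, -0.43 and -1.07 in rats 1 to 4. Camera called the list (median -0.75, adjusted p = 1.64e-06), with an adjusted p = 0.667 with an estimated correlation. The call of Ager was lost without rat 2 (adjusted p = 0.0690) or rat 4 (0.0569), and that of Timp3 without rat 2 (0.0522).

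Transitional epithelial markers, which mark cells between the type II and type I states, had 6 of 20 members lower and 2 higher (9 and 3 adjusted over the list alone). Areg, a ligand of the epidermal growth factor receptor, fell by 1.48 ± 0.15, the membrane protein gene Tm4sf1 by 1.31 ± 0.17 and the integrin subunit gene Itgb6 by 0.65 ± 0.09. The higher genes were Mdm2, the ubiquitin ligase of p53 (0.89 ± 0.17), and, outside the naming rule, the cyclin-dependent kinase inhibitor Cdkn1a (0.75 ± 0.14). The list was not called (median -0.14, camera adjusted p = 0.128; fry 0.0350). Calls were lost for Tm4sf1 without rat 2 (adjusted p = 0.0525), for Itgb6 without rat 2 or 4 (0.0739 and 0.0696) and for Mdm2 without rat 2, 3 or 4 (0.120, 0.0658 and 0.114).

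**Figure D2:**
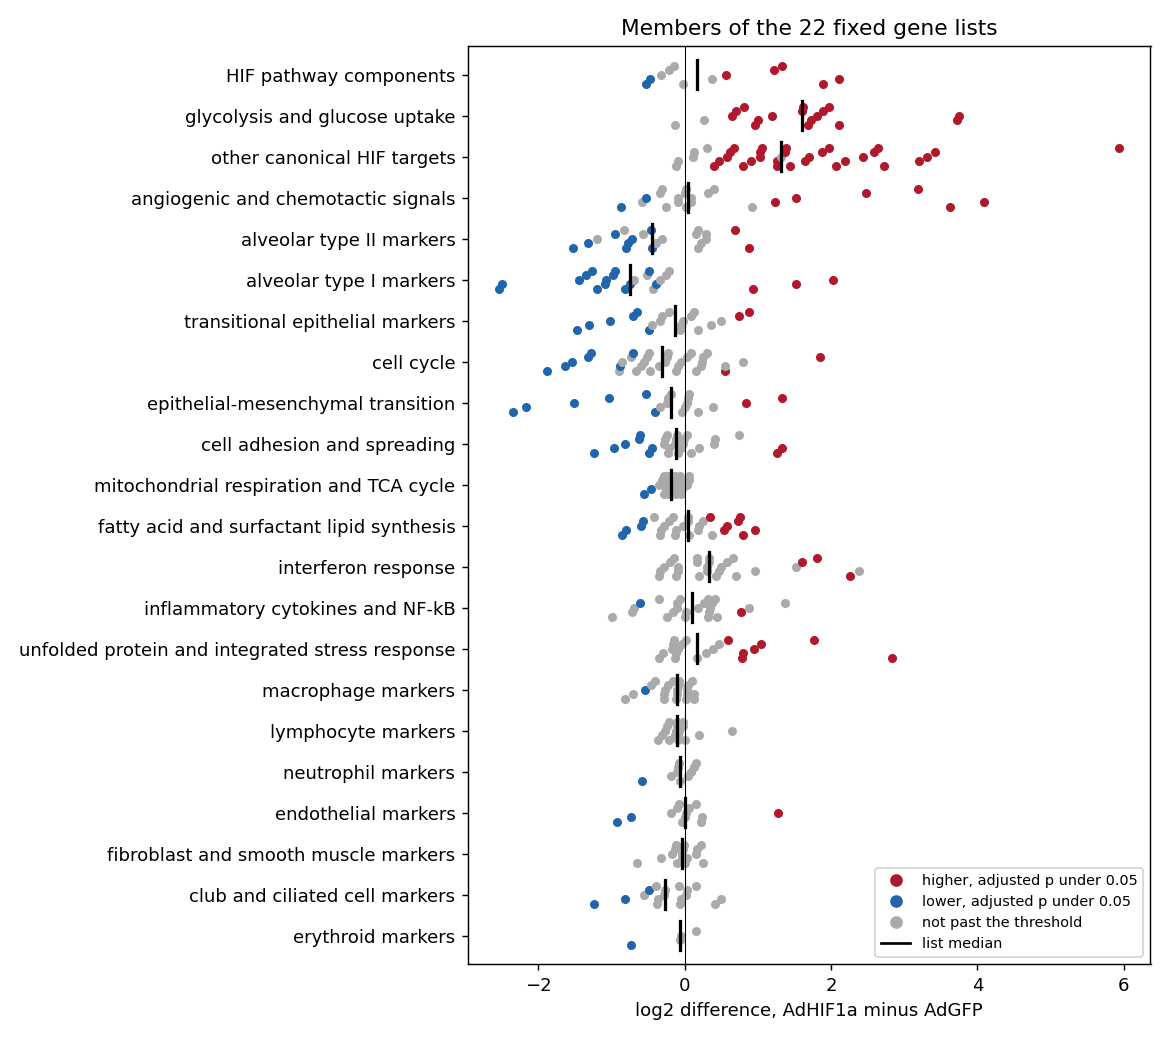
Log2 difference, AdHIF1a minus AdGFP (horizontal axis), of every measured member of the 22 gene lists, with red points for genes higher and blue points for genes lower at an adjusted p under 0.05, grey points for the rest and a black bar for the list median. The medians of the glycolysis list (1.61) and of the other HIF targets (1.31) lie farthest to the right and that of the type I markers (-0.75) farthest to the left.

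Cell cycle genes showed 7 of 34 measured members lower and 2 higher, and 12 lower and 4 higher adjusted over the list alone. Rrm2, a subunit of ribonucleotide reductase, fell by 1.88 ± 0.35, the proliferation marker Mki67 by 1.55 ± 0.34, the mitotic kinase gene Cdk1 by 1.28 ± 0.22 to a signal near the floor (4.72) and Plk1 by 0.89 ± 0.17. The higher genes were Cdk2, a kinase of DNA replication (0.55 ± 0.10), and, outside the naming rule, the replication licensing gene Cdc6 (1.85 ± 0.38). List medians were 0.17 in rat 1, and -0.46, -0.32 and -0.50 in rats 2 to 4. Of the 8 splits that part the wells of all 4 rats, 2 gave a list median at least as far from 0 as the real -0.31, with 0.40 the largest other in size. In rat 1 the macrophage markers also had a median of -0.66. Camera called the list (median -0.31, adjusted p = 0.0283), with an adjusted p = 0.751 with an estimated correlation, and not with quantile normalization (0.0831), with either filter on dim probe sets (0.0513 and 0.185), with fry (0.340) or without rat 2, 3 or 4 (0.0573, 0.0904 and 0.0538). Calls of Rrm2, Mki67, Cdk1, Plk1 and Cdk2 were each lost without rat 2, 3 or 4, at adjusted p from 0.0762 to 0.161, and that of Cdk2 after median centring (0.10).

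Genes of epithelial-mesenchymal transition were lower for 6 of 19 and higher for 2 (6 and 3 adjusted over the list alone). Tagln and Sparc, both mesenchymal genes, fell by 2.35 ± 0.23 and 2.17 ± 0.20, while Itga5, a subunit of the fibronectin receptor, rose by 1.33 ± 0.11 and Snai1, a repressor of E-cadherin, by 0.84 ± 0.10 from a low signal of 4.32 ± 0.22 (SD). Cell adhesion and spreading genes were lower for 7 of 27 and higher for 2 (8 and 5 adjusted over the list alone). Plau, the urokinase gene, fell by 1.23 ± 0.13 and the laminin subunit gene Lama3 by 0.96 ± 0.15. The collagen receptor subunit gene Itga1 rose by 1.26 ± 0.20 from 4.14 ± 0.21 (SD). Neither list was called (medians -0.19 and -0.11, camera adjusted p = 0.128 and 0.151), although fry called the first (0.0316). Calls were lost for Snai1 without rat 2 (adjusted p = 0.0572), for Lama3 without rat 2 or 4 (0.0819 and 0.0711) and for Itga1 without rat 2 or 4 (0.0543 and 0.0887).

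Genes of mitochondrial respiration and the tricarboxylic acid cycle had 2 of 30 members lower and 28 not past the threshold, with 2 lower and 0 higher adjusted over the list alone. These were Sdhb, a subunit of succinate dehydrogenase (-0.46 ± 0.09), and Ppargc1a, a co-activator of mitochondrial genes (-0.56 ± 0.11). List medians were 0.06 in rat 1, and -0.30, -0.20 and -0.27 in rats 2 to 4. The list was called by camera with a small median of -0.18 (adjusted p = 0.00319), with an adjusted p = 0.717 with an estimated correlation and 0.128 with fry, and 2 of the 8 splits that part all 4 rats gave a median as far from 0 (largest other 0.20 in size). Calls of Sdhb and Ppargc1a were lost without rat 2, 3 or 4 (adjusted p from 0.104 to 0.145), and that of Ppargc1a without the rat as a block (0.0623). Fatty acid and surfactant lipid synthesis genes had 7 of 27 members higher and 4 lower, or 8 and 7 adjusted over the list alone. Chpt1, the last enzyme of phosphatidylcholine synthesis, rose by 0.96 ± 0.11 and Gpam, the first enzyme of glycerolipid synthesis, by 0.79 ± 0.11. The sterol synthesis genes Idi1 and Cyp51 fell by 0.85 ± 0.13 and 0.59 ± 0.08, as did, outside the naming rule, Lpcat1 (-0.80 ± 0.15), which remodels surfactant phospholipid, and the elongase gene Elovl5 (-0.58 ± 0.12). That list was not called (median 0.04, camera adjusted p = 0.651). Calls were lost for Gpam without rat 4 (adjusted p = 0.0632), for Cyp51 without rat 2 or 4 (0.0792 and 0.0697) and for Idi1 without rat 2, 3 or 4 (0.0687, 0.0547 and 0.0812).

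Interferon response genes had 3 of 27 members higher and 0 lower, and 5 higher and 1 lower adjusted over the list alone. The chemokine genes Cxcl10 and Cxcl11 rose by 2.27 ± 0.46 and 1.81 ± 0.38 and the antiviral gene Oasl by 1.60 ± 0.36. The largest difference of the list, in the antiviral gene Rsad2, was 2.39 ± 0.58 (adjusted p = 0.0513), with within-rat differences from 0.73 in rat 1 to 4.05 in rat 4. Rsad2 passed in 9 alternatives, among them those without the rat as a block (0.0375), after median centring (0.0241) and without rat 1 (0.0398). The spread lay mainly in the AdGFP wells, where Cxcl10 stood at 9.76 ± 1.11 (SD) against 12.03 ± 0.15 in the AdHIF1a wells. List medians were 0.01, 0.73, 0.04 and 0.70 in rats 1 to 4, and 3 of the 8 splits that part all 4 rats gave a list median at least as far from 0 as the real 0.33 (largest other 0.39 in size). The list was called by camera (median 0.33, adjusted p = 0.0102), with an adjusted p = 0.717 with an estimated correlation, 0.345 with fry and 0.0686 without rat 2. Calls of Cxcl10 and Oasl were lost without rat 2, 3 or 4 and that of Cxcl11 when any 1 of the 4 rats was left out (adjusted p from 0.0529 to 0.163).

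Of 24 measured inflammatory cytokine and NF-kB genes, 1 rose and 1 fell (2 and 2 adjusted over the list alone). Lif, a cytokine of the interleukin-6 family, rose by 0.77 ± 0.15 and Icam1, an adhesion molecule for leukocytes, fell by 0.61 ± 0.10. The neutrophil chemokine gene Cxcl2 differed by 1.38 ± 0.34 (adjusted p = 0.0549), and passed after median centring (0.0293), with the filter at the median (0.0373), with array weights (0.0302) and with the trended prior (0.0363). The list was not called (median 0.10, camera adjusted p = 0.587). The call of Lif was lost when any 1 of the 4 rats was left out and that of Icam1 without rat 2, 3 or 4 (adjusted p from 0.0514 to 0.0988).

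Genes of the unfolded protein and integrated stress responses were higher for 7 of 21 and lower for 0, with 9 higher adjusted over the list alone. Vldlr, a lipoprotein receptor gene in this list, rose by 2.83 ± 0.11, Trib3, a pseudokinase, by 1.77 ± 0.09, and the transcription factor genes Cebpb and Atf3 by 1.04 ± 0.11 and 0.95 ± 0.11. Camera called the list (median 0.17, adjusted p = 0.0204), with an adjusted p = 0.716 with an estimated correlation and 0.0613 without rat 1.

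Markers of other cell types were mostly not past the threshold. Of 22 macrophage markers 1 was lower (0 adjusted over the list alone), the membrane receptor gene Adgre1 (-0.54 ± 0.12), and Mrc1, the mannose receptor, differed by -0.82 ± 0.21 (adjusted p = 0.0586, and 0.0320 to 0.0464 in the 5 alternatives that called it). Adgre1 lay near the floor in both groups (4.37 with AdGFP and 3.83 with AdHIF1a). The macrophage median was -0.11 over rats, with -0.66 in rat 1 and -0.005, -0.02 and 0.01 in rats 2 to 4, and the list passed camera without rat 2, 3 or 4 (adjusted p = 0.0435, 0.0320 and 0.0321) but pointed the other way without rat 1 (0.858). The call of Adgre1 was lost without the rat as a block, with a random block, after quantile normalization or median centring and without rat 2, 3 or 4 (adjusted p from 0.0521 to 0.161). Of 18 lymphocyte markers 0 were called (0 adjusted over the list alone), with Cd3e at -0.36 ± 0.14 and Cd3g at -0.21 ± 0.09 (adjusted p = 0.168 and 0.197). Of 10 neutrophil markers 1 was lower (1 adjusted over the list alone), S100a9, from a signal near the floor of 4.05 ± 0.18 (SD) by -0.59 ± 0.10. Of 16 fibroblast and smooth muscle markers 0 were called (0 adjusted over the list alone), with Des at -0.65 ± 0.23 and Fbln1 at -0.32 ± 0.11 (adjusted p = 0.133 and 0.124), of which Des passed without rat 3 (0.0378).

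Endothelial markers had 1 of 13 members higher and 2 lower (1 and 2 adjusted over the list alone). Plvap, a protein of endothelial fenestrae, rose by 1.27 ± 0.13, while the junction protein gene Esam fell by 0.93 ± 0.09 and Ramp2, a receptor partner for adrenomedullin, by 0.73 ± 0.17. The endothelial median was 0.0075 and the mean -0.0073. Of 17 club and ciliated cell markers 3 were lower and 0 higher (3 lower and 1 higher adjusted over the list alone), the ciliary genes Tppp3 (-1.23 ± 0.19), Tekt1 (-0.81 ± 0.10) and Ccdc39 (-0.48 ± 0.09), with a list median of -0.27. The only call among 4 erythroid markers was a fall of the globin gene Hbb-b1 (-0.74 ± 0.13), also the only one adjusted over the list alone. Camera did not call any of the 7 lists of other cell types, with adjusted p of 0.0900 for macrophage, 0.195 for lymphocyte, 0.617 for neutrophil, 0.951 for endothelial, 0.838 for fibroblast, 0.0824 for club and ciliated cell and 0.596 for erythroid markers. Club and ciliated markers passed without rat 3 (0.0375) and with fry (0.0120), and erythroid markers with fry (0.0316). The call of S100a9 was lost without rat 2, 3 or 4, those of Tekt1 and Tppp3 without rat 2 or 4, that of Hbb-b1 without rat 1, 2 or 3, those of Ramp2 and Ccdc39 when any 1 of the 4 rats was left out, and that of Ramp2 after quantile normalization (adjusted p from 0.0503 to 0.142).

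**Figure D3:**
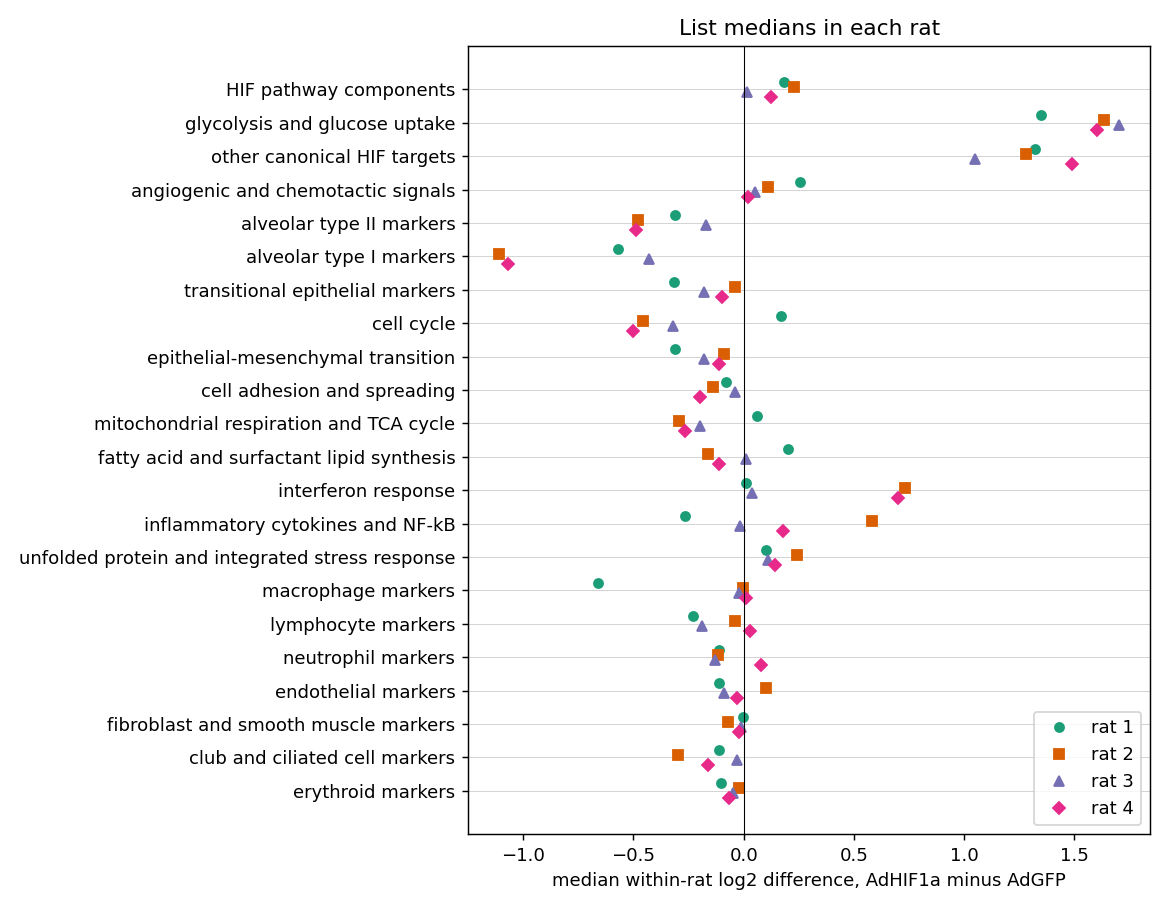
Median log2 difference within each rat, AdHIF1a minus AdGFP (horizontal axis), of the 22 gene lists, with 1 symbol per rat. The glycolysis list and the other HIF targets lie above 1 in all 4 rats, the type I markers lie below 0 in all 4 rats, and the macrophage markers lie at -0.66 in rat 1 and between -0.02 and 0.01 in the others.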

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

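The splits for the counts of called genes and called lists and the second list of myeloid genes were tests planned before their results were seen; the split test of the type I markers and all other tests in this part were chosen after the result was seen.

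The wells labelled AdHIF1a differed from the AdGFP wells in 2443 genes, and of the 32 splits of the arrays with a contrast within rats 1 gave as many calls, the real one, with 0 as the highest of the others. All the other splits hold the virus difference in their residual spread, which lowers their counts of called genes. Only the 8 splits that part all 4 rats exchange labels within rats, as the pairing asks; 1 of these gave as many calls, the real one, with 0 as the highest other, and 8 splits are too few for a share under 0.05. Camera with the preset correlation called 7 lists, and 4 of these 8 splits gave at least as many, the highest other being 8 (10 of all 32 splits gave as many). By the rule set beforehand, a share of at least 0.05 of the 32 splits goes with chance, and these 10 met it. Another split can keep part of the virus difference in its contrast, so these counts do not measure chance alone. For the glycolysis list the largest median of another split was 0.84 in size, against 1.61 in the real one. Among the 8, however, the splits that exchange labels within 2 of the 4 rats cancel the average virus difference, and they called 2, 8 and 4 lists. The number of called lists therefore does not set the real grouping apart from other splits.

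The Hif1a probe set was lower by -0.48 in the wells labelled AdHIF1a, in 4 of 4 rats. An exchange of well labels is argued against by the other HIF targets, whose lowest median within a rat was 1.05. A scale difference left between the deposited arrays is argued against too, since the difference nearest 0 under the other scalings was -0.44. The arrays were already on a common scale, so these scalings could move a gene only a little, and effects of the scaling before deposit were not tested. It stays open whether the probe set reads the transgene at all, because neither sequence is given, and the difference of -0.48 alone cannot decide it. A decrease of the rat's own transcript under active HIF1a stays open and was not tested.

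Markers of type I cells had a median of -0.745. A smaller share of epithelial cells in the AdHIF1a wells, with more macrophages in their place, would have raised macrophage markers. Their highest median within a rat was 0.01, which argues against such an exchange. Macrophage markers cannot show the mix of cells within the epithelium, so that mix was not tested. A scale difference left between the deposited arrays is argued against by a median of -0.77 nearest 0 under the other scalings, which could move it only a little. Of the 8 splits that part all 4 rats, 1 gave a median as far from 0, the real one, with 0.583 as the largest other in size, and 8 splits are too few for a share under 0.05; for the called cell cycle, mitochondrial and interferon lists 2, 2 and 3 of the 8 did. A response of the epithelial cells to active HIF1a stays open and was not tested.

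The macrophage markers stood apart in rat 1, with a median within-rat difference of -0.66 against -0.02 to 0.01 in the other rats, and 15 of the 22 markers were lowest there. A larger share of macrophages in the AdGFP than in the AdHIF1a well of rat 1 may be a cause; the median marker level was 6.17 in that AdHIF1a well, the lowest of all 8, and 6.89 in its AdGFP well, within the 6.86 to 7.86 of the other AdGFP wells, and of the most abundant markers Cybb (9.85) and Fcer1g (9.66) differed by -0.75 and -1.01 in rat 1 but Lcp1 (11.63) by -0.02. A second list of myeloid genes had a median of -0.295 in rat 1 against -0.055, 0.065 and 0.135 in rats 2 to 4, with 16 of its 26 measured genes lowest in rat 1. This fell just short of the bound of -0.3 set for it, so the explanation stays undecided. A scale difference left between the deposited arrays of rat 1 is argued against by a median difference of 0 over all genes. No sort or gate is named in the labels, and no biological explanation was tested.

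Single wells stood far from the other 3 wells of their group for 9 of the named genes. Along with the list medians, 11 such values arose among 214 groups of 4, about the 1 in 20 that chance gives. Cxcr4 was 8.92 in the AdHIF1a well of rat 1 against 8.09 to 8.16 in the others. The AdGFP well of rat 1 was highest for Cxcr4 too (6.45 against 5.54 to 5.73). The within-rat difference of Cxcr4 was 2.47 in rat 1 and 2.43 to 2.55 in the others. Mdm2 was 9.51 (9.79 to 9.84), Snai1 was 4.79 (5.24 to 5.33) in the AdHIF1a well of rat 3, and Lif was 9.62 (10.05 to 10.13) in that of rat 4. In the AdGFP well of rat 1, Cdk1 was 5.23 (6.20 to 6.33), Rrm2 was 6.31 (8.05 to 8.29) and Atf3 was 9.69 (8.85 to 8.97). In the AdGFP well of rat 3, Itga5 was 7.89 (7.67 to 7.70) and Cd3g was 3.76 (4.13 to 4.20). Snai1, Atf3 and Cd3g lay at the same end of the group in the other well of the same rat as well. The median of the neutrophil markers was 0.08 in rat 4 against -0.13 to -0.11 in the others.

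Probe sets without a gene symbol, which no comparison used, also differed between the viruses. Here p was adjusted over all 36685 probe sets rather than over the 18166 genes. Of 17599 such probe sets, 457 were higher and 216 lower in the wells labelled AdHIF1a, or 3.82% against 10.7% of the probe sets with 1 symbol, and their median level was 4.36 against 6.26. Probe set 17788338 went from 2.65 to 7.29 (adjusted p = 0.00280) and probe set 17882399 from 5.33 to 9.78 (adjusted p = 0.000226). Probe sets 17881177 and 17881299 both went from 11.7 to 6.36 (difference -5.37, adjusted p = 0.00504), with the same means in both groups.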

How the results depend on the processing

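No alternative was chosen after seeing the data. Without the replicate block, 1279 genes were higher and 1672 lower, 2951 in all, of which 2266 were among the 2443 of the paired fit. Without the block, Sftpb, Ppargc1a and Adgre1 lost their calls, while Rsad2 and the lists of ATII markers and of angiogenic signals gained one. No other list and no other gene named by the rule changed its call. The genes named outside the rule were not followed through the alternatives. No shared call changed sign under any alternative fit. For the omission of a rat this had to be so, since each called gene moved the same way in 4 of 4 rats. Median centring left 635 higher genes (32.4% of calls higher, against 42.2%), an adjusted p under 0.01 left 349 higher and 307 lower, and a minimum of 1.5-fold left 656 and 924; stricter thresholds can only lower counts. Leaving out a rat gave 315 to 775 higher and 246 to 1231 lower genes, with fewer arrays and so less precision, and higher calls outnumbered lower ones without rat 2 or rat 4. Hif1a ranged from -0.52 to -0.46 when a rat was left out, missing the threshold without rat 2, 3 or 4, and from -0.56 with median centring to -0.44 with quantile normalization over all alternatives.

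For the lists, the estimated correlation left 1 of 7 called and fry called 11. With an estimated correlation the adjusted p was 0.0777 for glycolysis, 0.667 for type I markers, 0.751 for the cell cycle, 0.717 for mitochondrial and for interferon genes and 0.716 for the unfolded protein response. With fry it was 0.340 for the cell cycle, 0.128 for mitochondrial and 0.345 for interferon genes. The cell cycle list also missed the threshold with quantile normalization (0.0831) and with the filters at the median (0.185) and the lower quartile (0.0513). Without 1 rat, adjusted p ran from 2.04e-05 to 0.0904 for the cell cycle, from 0.000475 to 0.0686 for interferon genes and from 0.0111 to 0.0613 for the unfolded protein response. Of the lists not called, 4 turned direction when a rat was left out, lipid synthesis without rat 1 (0.858), inflammatory genes without rat 2 (0.657), macrophage markers without rat 1 (0.858) and endothelial markers without rat 2 (0.687). Over all 4 omissions, turned or not, their adjusted p ran from 0.306 to 0.858, 0.187 to 0.657, 0.0320 to 0.858 and 0.687 to 0.959. Endothelial markers also turned with quantile normalization (0.769) and fry (0.739). The neutrophil list had too few genes left for a value under the filter at the median. Where nothing above gives it, the cause was not tested. Signals close to the floor of the arrays, such as those of lymphocyte, neutrophil and endothelial markers, limit what can be seen in those lists.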

Other observations

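The gene groups in this part were chosen after the data were seen, and so were their tests.

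Of 15 measured genes of ion and fluid transport across the alveolar epithelium, 8 were lower in the wells labelled AdHIF1a, 0 were higher and 7 were not called, among them Sgk1 (0.42 ± 0.27), with the same counts adjusted over the list alone. The 3 subunits of the epithelial sodium channel all fell, Scnn1a from 11.43 to 10.07 (-1.36 ± 0.11), Scnn1b by 0.82 ± 0.14 and Scnn1g by 0.73 ± 0.13, as did the chloride channel genes Cftr (-0.55 ± 0.11) and Slc26a9 (-1.20 ± 0.13). The water channel genes Aqp4 and Aqp3 fell by 1.85 ± 0.19 and 1.46 ± 0.25, and Nedd4l, a ubiquitin ligase that removes the sodium channel from the membrane, by 0.54 ± 0.08. The list median was -0.54, with an adjusted p = 0.305 with an estimated correlation. Of 17 measured genes of prostaglandin synthesis and transport, Ptges, which makes prostaglandin E, rose by 2.57 ± 0.22, while the transporter gene Slco2a1 and Tbxas1 (-0.53 ± 0.12) fell and 14 were not called (adjusted p = 0.621 with an estimated correlation).

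Circadian clock genes were higher for 5 of 16 measured members and lower for 0, namely Ciart, Bhlhe41 (1.70 ± 0.14), Per2 and Nfil3 (both 1.08) and Rora (0.62 ± 0.14), while Clock (-0.02 ± 0.08) and Bmal1 (0.09 ± 0.08) were not called (adjusted p = 0.182 with an estimated correlation for the list). Bhlhe41 and Rora also belong to the list of other canonical HIF targets and were counted there, and Ciart was already named among the largest increases. The metallothionein genes Mt1 and Mt2A rose by 1.20 ± 0.12 and 1.47 ± 0.15, and of 8 genes in a list with zinc transporters 3 rose and 1 fell. That list's median was -0.13 while its camera test pointed up (adjusted p = 0.621 with an estimated correlation).

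The cell cycle list held genes that went apart. Of 18 genes of mitosis and G2/M, 6 fell and 0 rose (median -0.69), and of 13 genes of replication licensing and G1/S, 2 rose and 0 fell (median 0.24). Rrm2, Tyms and Ccnd1 of the cell cycle list were put in neither group. Rrm2, the ribonucleotide reductase subunit, was called and fell by 1.88 ± 0.35, so the contrast between the groups depends on how the genes were assigned. Medians in rats 1 to 4 were -0.04, -0.92, -0.83 and -1.06 for mitosis and 0.81, 0.02, -0.09 and 0.05 for replication, with adjusted p = 0.421 and 0.621 with an estimated correlation. Whether the difference between the lists exceeds chance was not tested.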
